A study of Homo sapiens with 6 samples.

How the data were processed

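Biotin-labelled cRNA from total RNA of Huh7 cells had been hybridised to Affymetrix HG-U133 arrays, per the labels' protocols, with 1 array for each of 6 cultures: 3 with HDL of normal subjects and 3 with HDL of FH subjects, at 70 ug/mL for 48 h. FH was read as familial hypercholesterolemia from knowledge of the study, since the labels give the abbreviation alone. Groups and replicate numbers were taken from the sample titles and the treatment label. The labels name no hybridisation or scan batch, so none was tested.

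The deposited values were a table of 1 value per probe set and array, taken as log2 expression because they lay between 0 and 13.8. The summarisation, background correction, normalization and log base were not given in the sources used here, so a fold given here holds only if the base is 2. The table held 45269 probe sets, 10 of them array controls. Of the 45259 others, the platform annotation used here listed 36141, of which 34631 had 1 gene symbol and 1510 several, and 9118 were not listed and are unnamed here. Symbols were updated through a RefSeq gene table of assembly GRCh38.p14, used for names alone, and no coordinates are given because no genome build applies to the values. The probe sets with 1 symbol named 17578 genes.

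Array medians differed by over 0.1, so the values were quantile normalized between arrays, by the rule set before the data were examined. Each gene was represented by its probe set with the highest mean over the 6 arrays. Genes under the 40th percentile of the mean of all probe sets (5.99) were left out, and 12840 genes were tested. FH HDL was compared with normal HDL with limma's linear model and empirical Bayes moderation, two-sided, without a block or covariate, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. A second count used an unadjusted p under 0.05 with a fold of at least 1.5, which is not corrected for multiple tests. Control probe sets served only for the array checks, and 2 genes of the rule below were not analysed here. R 4.3.3, limma 3.58.1 and, for plots, matplotlib were used.

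The 24 gene lists, for lipid metabolism, liver functions, inflammation, stress, cell cycle, clock, housekeeping machinery, microRNA silencing and markers of other cell types, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera with a correlation estimated for each list and the rotation test fry were run beside it. The named genes were, by a rule also fixed beforehand, the 12 largest changes in each direction among called genes without overlap between the groups, up to 4 members of each list with the smallest unadjusted p, and a few genes of lipid transport and liver. The rule gave 120 genes, 103 of them called, and the text gives a selection of them. SREBF2, PDIA4, NQO1 and NPAS2 were chosen after their values were seen, because each stands in a count of 5 or fewer. Of the 120, 56 had several probe sets past the filter, and 4 (LPCAT3, DNAJB1, SCARB1 and ALB) had a probe set called in the direction opposite to the one used.

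The fit was tested on a simulation of 3 against 3 arrays over 12840 genes. Known changes of 1.2-fold, 1.5-fold and 2-fold were given to 67, 67 and 66 genes. The fit recovered 13.4% of genes changed by 1.2-fold, 53.7% of those changed by 1.5-fold and 80.3% of those changed by 2-fold, with 2 false calls among 100. The simulation changed far fewer genes than the 32.9% called in the data, and its noise was independent between genes. An adjusted p depends on the share of genes changed, so these rates are not those of the real comparison. Alternatives were other filters, scalings and probe set summaries, the options of the moderated fit, the replicate number as a block, array weights and leaving out each array. A fit without probe sets of the shared-target types and a fit with the ACTB control difference as a covariate were added after the data were seen. A planned test of genes with microRNA seed sites was not run, because it needs 3′ untranslated sequences that were not used here. The alternative pseudocount was not needed, since the values were on a log scale.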

Results

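Gene expression was measured in Huh7 cells, a human hepatoma line, after 48 h with high-density lipoprotein (HDL) at 70 ug/mL in medium with 10% lipoprotein-depleted serum. HDL came from normal subjects for 3 arrays and from subjects with FH for the other 3. The series concerns microRNAs that HDL carries to recipient cells, and the design asks which mRNAs differed between cells given the 2 kinds of HDL. The labels call the arrays biological replicates without saying whether each culture received HDL of a different subject or of a pool, so the p-values measure only the spread between these cultures. Array medians lay between 6.44 and 6.58 on the deposited scale, taken as log2 from its range. The mean correlation of an array with the others of its group was 0.959 to 0.963 for normal HDL and 0.974 to 0.975 for FH HDL. That with the arrays of the other group was 0.955 to 0.964 for normal HDL and 0.957 to 0.959 for FH HDL. Normal HDL replicate 2 correlated slightly more with the FH HDL arrays (0.9643) than with its own group (0.9625). The 3′ minus 5′ difference of the ACTB control probe sets, a sign of RNA integrity and labelling, was 1.36 ± 0.07 with normal HDL and 1.13 ± 0.13 with FH HDL (log2, SD, n = 3 each). That of GAPDH was 0.09 ± 0.02 and -0.03 ± 0.03. Neither control's values overlapped between the groups, and the exact two-sided permutation p was 0.1 for both, the smallest that 3 against 3 arrays allow. The number of arrays limits the precision of every value given here.

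With FH HDL, Huh7 cells had more mRNA for the machinery of DNA replication and for enzymes of cholesterol synthesis than with normal HDL, and less for metallothioneins, for stress-response genes and for antioxidant genes. These 5 gene lists passed a gene set test with a preset correlation between genes, and none did with a correlation estimated from these arrays (adjusted p from 0.25 to 0.343 with an estimated correlation). UHRF1, which helps to maintain DNA methylation at replication, was 3.14-fold higher (log2 difference 1.65 ± 0.12 SE, n = 3 each). PDK4, a kinase that inhibits pyruvate dehydrogenase, was 2.60-fold lower (-1.38 ± 0.12 SE). In all, 2295 of 12840 genes tested were higher with FH HDL and 1931 lower at a limma adjusted p under 0.05, which is 32.9% of the genes. Most of the changes were small: the median size among changed genes was 1.27-fold, 29 changed genes rose by over 2-fold and 33 fell by over 2-fold. Under a rule of at least 1.5-fold with an unadjusted p under 0.05, 345 genes were higher and 273 lower. The values of the 3 arrays of each group did not overlap for 49.5% of genes, against 10% by chance. Without FH HDL replicate 3, the adjusted counts dropped to 1343 higher and 1233 lower. With the ACTB control difference of each array in the fit as a covariate, they were 335 and 367.

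**Figure D1:**
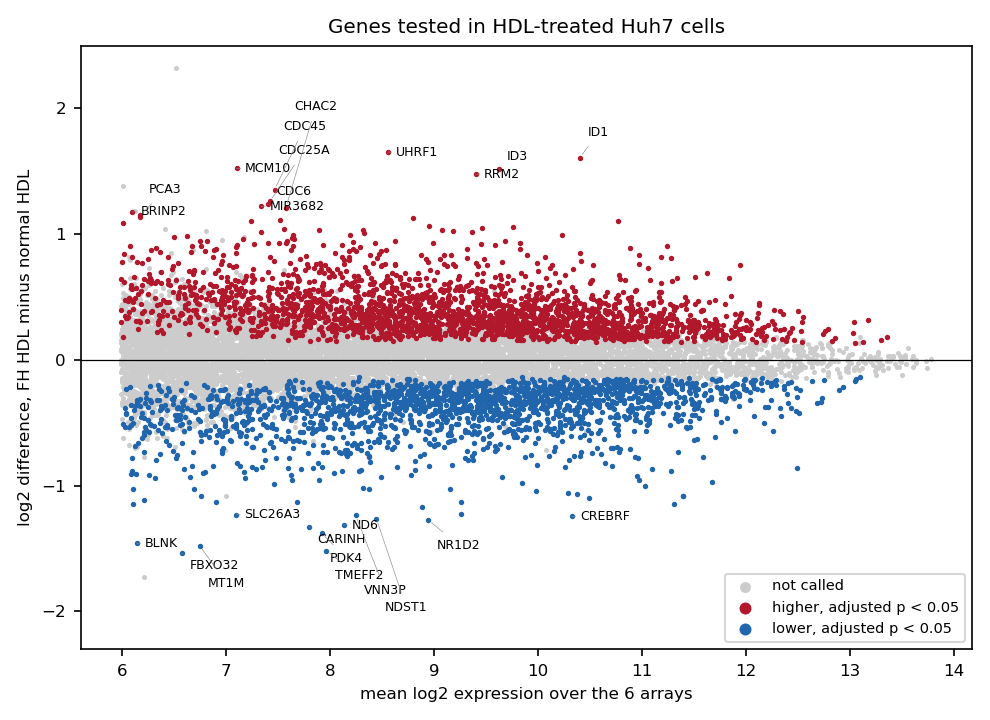
Each point is 1 of the 12840 genes tested, with the mean log2 expression over the 6 arrays on the x axis and the log2 difference of FH HDL minus normal HDL (3 arrays each) on the y axis. Red points were higher and blue points lower at an adjusted p under 0.05, grey points were not called, and the 12 largest rises and 12 largest falls among called genes without overlap between the groups are named.

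Among the largest rises were those of MCM10 (log2 difference 1.52), CDC45 (1.35) and CDC6 (1.24), which act at replication origins, of RRM2 (1.48), a subunit of ribonucleotide reductase, and of CDC25A (1.26), a phosphatase that activates cyclin-dependent kinases. MCM10, CDC45 and CDC25A are not members of the DNA replication list tested here. ID1 (1.61 ± 0.08 SE) and ID3 (1.51 ± 0.10 SE), which block basic helix-loop-helix transcription factors, were both among the 4 largest rises of called genes. CHAC2, an enzyme that degrades glutathione, rose by 1.21, BRINP2 by 1.18 and the noncoding RNA PCA3 by 1.15. A probe set annotated to MIR3682 rose by 1.22, and such a probe set does not measure the mature microRNA. A further CDC25A probe set gave -0.01, so that rise rests on 1 of its 2 probe sets.

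FBXO32, a muscle-atrophy ubiquitin ligase, had the largest measured fall among called genes without overlap between the groups, at 2.90-fold (log2 difference -1.54 ± 0.07 SE), on 1 of 2 probe sets. Its mean with FH HDL (5.80) and that of BLNK (5.41) lay under the filter value of 5.99, as did the means with normal HDL of BRINP2 (5.50), PCA3 (5.60) and CD14 (5.82), so the sizes of these changes are uncertain. MT1M, a metallothionein, gave -1.48 and BLNK, an adaptor of B-cell receptor signalling, gave -1.46. The nuclear receptor gene NR1D2, a repressor in the circadian clock, fell by 1.27 and CREBRF, a regulator of the transcription factor CREB3, fell by 1.25. CREBRF was lower in all 5 of its probe sets. Other large falls were those of CARINH (-1.33), the mitochondrially encoded ND6 (-1.31), NDST1 (-1.27), the vanin pseudogene VNN3P (-1.24) and the anion exchanger SLC26A3 (-1.23). The falls of CARINH and NDST1 each rest on 1 probe set, and another probe set gave 0.06 and -0.01. TMEFF2 (-1.52 ± 0.35 SE) was not called without FH HDL replicate 2 (-1.33, adjusted p = 0.0671) or without FH HDL replicate 3 (-1.60, adjusted p = 0.055).

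DNA replication genes were higher with FH HDL. Of 19 list members, 17 rose and 0 fell, with the same counts adjusted over the list alone, and the median difference was 0.83, or 1.78-fold. PCNA, the sliding clamp of DNA polymerases, was 2.15-fold higher (1.10 ± 0.05 SE, adjusted p = 0.000639), and the helicase subunits MCM4 (1.02) and MCM6 (0.99) rose by similar amounts. The list passed camera, limma's competitive gene set test (adjusted p = 8.36e-09), but not with the correlation between genes estimated from these arrays (adjusted p = 0.343 with an estimated correlation). Mitosis genes moved less: 12 of 20 rose and 0 fell, 14 rose adjusted over the list alone, and the median was 0.29. BIRC5, an inhibitor of apoptosis in dividing cells, rose by 0.80, the kinase gene AURKB by 0.53, CENPF by 0.43 and NUSAP1 by 0.45, on 1 of 2 probe sets with the other at -0.031. Camera called the mitosis list (adjusted p = 8.33e-05; adjusted p = 0.391 with an estimated correlation). With the ACTB control difference, 1.36 with normal HDL and 1.13 with FH HDL, as a covariate, 10 replication genes and 1 mitosis gene rose, while the medians were 0.86 and 0.29 and camera called both lists (adjusted p = 3.91e-08 and 0.00658). The median SE of a gene of each list was 0.14 in that fit, against 0.08 without the covariate. Without FH HDL replicate 3, 7 mitosis genes rose and the median was 0.30.

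**Figure D2:**
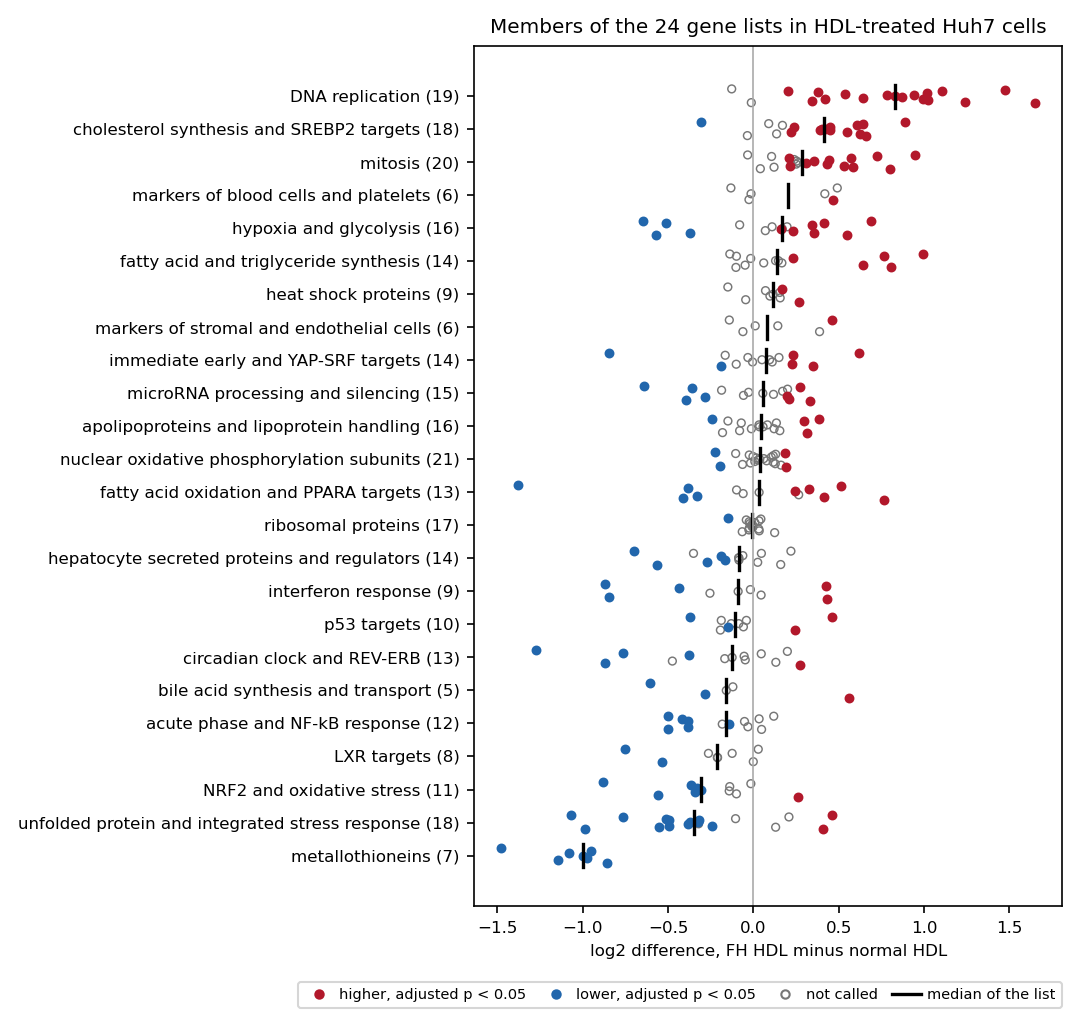
Each point is a gene of 1 of the 24 lists fixed before the data were examined, at its log2 difference of FH HDL minus normal HDL (3 arrays each), with the number of tested members after the name of the list and lists ordered by their median (black line). Red points rose and blue points fell at an adjusted p under 0.05, and open points were not called; DNA replication has the highest median (0.83) and metallothioneins the lowest, at 2.00-fold lower with FH HDL.

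Genes of cholesterol synthesis were higher with FH HDL as a group. Of 18 tested members of the list of synthesis genes and targets of the transcription factor SREBP2, 13 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone, with a median of 0.41. FDPS, which makes farnesyl diphosphate, was 1.58-fold higher (0.66 ± 0.06 SE, adjusted p = 0.00141), and ACAT2 (0.63), EBP (0.61) and LSS (0.55) rose by similar amounts. Of the 3 probe sets of EBP 1 gave -0.48 and was not called. The 1 member called lower was SREBF2 (-0.31), the gene of SREBP2 itself, on 1 of 3 probe sets, the highest of which gave 0.027. It was not called without normal HDL replicate 1 or 2 or without FH HDL replicate 1 or 3. Camera gave an adjusted p of 2.40e-05 for the list, and adjusted p = 0.25 with an estimated correlation. In fatty acid and triglyceride synthesis, 5 of 14 genes rose and 0 fell, and 6 rose adjusted over the list alone: the desaturase FADS2 (0.99), the elongase ELOVL6 (0.81), fatty acid synthase FASN (0.77) and acetyl-CoA carboxylase ACACA (0.64) led them. The FADS2 and ACACA rises each rest on 1 of 2 probe sets, and the list did not pass (adjusted p = 0.0982). With the ACTB control difference (1.36 and 1.13 in the 2 groups) as a covariate, 6 genes of the cholesterol list and 1 of the fatty acid list rose, while the medians were 0.40 and 0.13, against 0.41 and 0.14, and camera called the cholesterol list (adjusted p = 2.83e-05). The median SE of a gene was 0.10 and 0.12 in that fit, against 0.06 and 0.08. The cholesterol median was 0.22 with the mean of a gene's probe sets and 0.26 without probe sets of the shared-target types, where that of the fatty acid list was 0.0021.

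Targets of the oxysterol receptor LXR did not pass as a group (adjusted p = 0.0527; adjusted p = 0.391 with an estimated correlation), with 0 of 8 higher and 2 lower, also adjusted over the list alone. SMPDL3A, a phosphodiesterase induced by LXR, fell by 0.75 and the sterol exporter ABCG1 fell by 0.53, on 1 of 2 probe sets with the other at -0.043. The cholesterol exporter ABCA1 was not called at -0.12 ± 0.07 SE, and the other of its 2 probe sets was called lower at -0.46. The LXR list passed in 6 of 18 alternatives with a preset correlation, at an adjusted p from 0.00764 to 0.24 over the 18. These were the fits without normal HDL replicate 2 (adjusted p = 0.0398), FH HDL replicate 2 (0.0335) or FH HDL replicate 3 (0.0212), both other scalings (0.0439 as deposited and 0.0346 median-centred) and the ACTB covariate (0.00764), where its median was -0.32 against -0.21, the control difference being 1.36 with normal HDL and 1.13 with FH HDL. Of 16 apolipoprotein and lipoprotein-handling genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.734). APOM (0.39 ± 0.07 SE), APOA1, the main protein of HDL (0.32 ± 0.07 SE), and MTTP (0.30 ± 0.04 SE) rose and VLDLR fell by 0.24. APOA1 lost its call without normal HDL replicate 2 (0.31, adjusted p = 0.0518). VLDLR lost its call without normal HDL replicate 1 or 3 or FH HDL replicate 1 or 3, at -0.25 to -0.21 (adjusted p from 0.0546 to 0.0741). With the ACTB covariate 0 of these 16 genes rose and 0 fell, and the median was 0.0027 against 0.046. The median SE of a gene was 0.10 in that fit, against 0.06. The HDL receptor gene SCARB1 was not called at 0.16 ± 0.07 SE, and its 4 probe sets ranged from -0.53 to 0.31.

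Of 13 genes of fatty acid oxidation and the nuclear receptor PPARA, 5 rose and 4 fell, and 6 rose and 4 fell adjusted over the list alone. FABP1, the liver fatty acid-binding protein, rose by 0.76 and the dehydrogenase ACADVL by 0.41, while PDK4 fell by 1.38 and the lipid droplet coat gene PLIN2 by 0.38. The list was not called (adjusted p = 0.994), its median being 0.03 and its mean -0.01. Of 5 tested bile acid genes, 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.25). The nuclear receptor gene NR0B2, which restrains bile acid synthesis, fell by 0.60, CYP27A1 fell by 0.28 and the hormone gene FGF19 rose by 0.56. CYP27A1 lost its call without normal HDL replicate 2 or 3 or FH HDL replicate 1 or 3, at -0.27 to -0.24 (adjusted p from 0.0512 to 0.077).

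All 7 tested metallothioneins, small proteins that bind zinc and copper, were lower with FH HDL, also adjusted over the list alone. By the median of the list they were 2.00-fold lower. MT2A was 1.82-fold lower (-0.86 ± 0.05 SE, adjusted p = 0.000669), MT1E fell by 0.97, MT1F was 2.00-fold lower and MT1H fell by 1.15. Camera called the list (adjusted p = 9.96e-07), and adjusted p = 0.27 with an estimated correlation. These genes are near-identical in sequence, and 1 of them, MT1M, was measured by a probe set of the type without shared targets, so the members cannot be taken as separate measurements. With the ACTB covariate (control difference 1.36 with normal HDL, 1.13 with FH HDL), 5 of the 7 were lower, with a median of -1.02 and a median SE of a gene of 0.15, against 0.08 without it.

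Stress-response genes were lower as a group. In the list of the unfolded protein and integrated stress responses, 12 of 18 genes fell and 2 rose, and 13 fell and 3 rose adjusted over the list alone, with a median of -0.35. DDIT3, the transcription factor CHOP, was 2.09-fold lower (-1.07 ± 0.05 SE, adjusted p = 0.000639), CHAC1 fell by 0.98 and HERPUD1, which acts in degradation from the endoplasmic reticulum, fell by 0.76. The 2 that rose, CALR (0.46) and PDIA4 (0.41), encode chaperones of the endoplasmic reticulum. Of 11 targets of the oxidative stress regulator NRF2, 6 fell and 1 rose, also adjusted over the list alone, with a median of -0.30. OSGIN1 fell by 0.88, the cystine transporter gene SLC7A11 by 0.56, GCLM, of glutathione synthesis, by 0.37 and SRXN1 by 0.34, while NQO1 rose by 0.26. Camera called both lists (adjusted p = 0.000285 and 0.00204), and neither with an estimated correlation (adjusted p = 0.25 and adjusted p = 0.343). With the ACTB covariate (control difference 1.36 and 1.13 in the 2 groups), 4 stress genes and 2 NRF2 targets fell, while the medians were -0.38 and -0.30, camera called both lists (adjusted p = 0.000112 and 0.00658) and the median SE of a gene was 0.09 in each, against 0.06 and 0.05. With the mean of a gene's probe sets 8 of the 18 stress genes fell and 3 rose, with a median of -0.25 (adjusted p = 0.0212). In that fit the NRF2 median was -0.14, with a median SE of 0.08, and the list was not called (adjusted p = 0.0689).

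**Figure D3:**
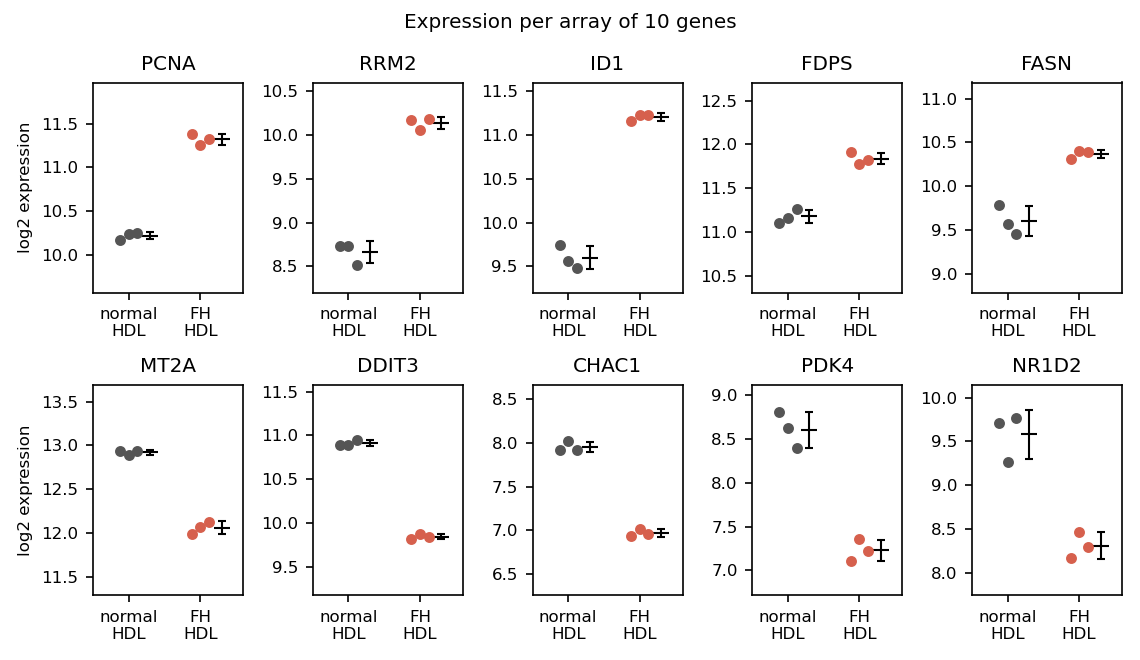
Each panel plots 1 gene, with log2 expression of the 3 arrays of normal HDL (grey) and the 3 of FH HDL (red), and the mean with its SD (black) beside them, every y axis spanning the same log2 range. PCNA, RRM2, ID1, FDPS and FASN were higher and MT2A, DDIT3, CHAC1, PDK4 and NR1D2 lower with FH HDL, without overlap between the groups.

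Acute phase and NF-kB genes were lower where they changed: 6 of 12 fell and 0 rose, also adjusted over the list alone, with a median of -0.16. The plasma protein genes ORM1 (-0.50) and HP (-0.50) and the NF-kB targets TNFAIP3 (-0.39) and CXCL2 (-0.38) were among them. Camera called this list (adjusted p = 0.0149; adjusted p = 0.343 with an estimated correlation). The call was lost with the mean of a gene's probe sets (adjusted p = 0.127) and without probe sets of the shared-target types (0.138, over 7 genes), where the median was again -0.16 and the median SE of a gene was 0.06 and 0.11, against 0.06. It was also lost with the ACTB covariate (adjusted p = 0.091), where the median was -0.064 and the median SE 0.10, the control difference being 1.36 with normal HDL and 1.13 with FH HDL. Of 9 interferon-response genes, 3 fell and 2 rose, and 4 fell and 2 rose adjusted over the list alone (adjusted p = 0.246). IFIT2 (-0.87), IFIT3 (-0.85) and MX1 (-0.43) fell, and OAS1 rose by 0.43. Without any 1 array other than normal HDL replicate 1, 1 gene of this list rose.

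Of 14 genes of secreted hepatocyte proteins and their regulators, 5 fell and 0 rose, and 6 fell and 2 rose adjusted over the list alone. The fibrinogen chain gene FGA fell by 0.70 and the transcription factor gene FOXA3 by 0.57. ALB, the gene of albumin, was not called at -0.09 ± 0.05 SE, and its 4 probe sets ranged from -0.54 to 0.19. Without FH HDL replicate 2, 4 fell, and without any 1 of the other arrays 3 fell. The list was not called (adjusted p = 0.07; adjusted p = 0.391 with an estimated correlation) and passed in 4 of 18 alternatives with a preset correlation (adjusted p from 0.0381 to 0.447). These were the fits without FH HDL replicate 3 (adjusted p = 0.0426), with median-centred arrays (0.0455), a mean-variance trend (0.04998) or the ACTB covariate (0.0381). In the circadian clock list, 4 of 13 genes fell and 1 rose, also adjusted over the list alone. Beside NR1D2, NFIL3 fell by 0.87, RORA by 0.76 and TEF by 0.38. The 1 called higher, NPAS2 (0.27), was not called without normal HDL replicate 2 or 3 or without any 1 array of FH HDL. This list missed the threshold (adjusted p = 0.0527; adjusted p = 0.479 with an estimated correlation) and passed it in 11 of 18 alternatives with a preset correlation, at an adjusted p from 0.00116 to 0.143 over the 18. It passed without normal HDL replicate 2 (adjusted p = 0.0472) or 3 (0.0282) or FH HDL replicate 2 (0.0335) or 3 (0.0426), but not without normal HDL replicate 1 (0.143) or FH HDL replicate 1 (0.0716). With the mean of a gene's probe sets (adjusted p = 0.00116) 6 of 11 genes fell and the median was -0.38 against -0.12, and with the ACTB covariate (0.00658) 3 fell and it was -0.19.

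The remaining lists went both ways or changed little. In hypoxia and glycolysis, 7 of 16 genes rose and 4 fell, and 8 rose and 4 fell adjusted over the list alone (adjusted p = 0.434), with PDK1 higher (0.69, on 1 of 2 probe sets with the other at -0.019) and NDRG1 (-0.65) and HK2 (-0.57) lower. With the ACTB covariate 1 of the 16 rose and 1 fell, while the median was 0.16, against 0.17. The median SE of a gene was 0.11 in that fit, against 0.06. Among 14 immediate early and YAP-SRF targets 4 rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone (adjusted p = 0.8), with MYC, a growth-promoting transcription factor, 1.80-fold lower (-0.85 ± 0.05 SE) and IER2 higher (0.35). Without FH HDL replicate 1 or 3, 1 of these genes rose, without normal HDL replicate 2, 2 rose, and without any 1 array other than FH HDL replicate 1, 1 fell. Of 10 p53 targets, 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.427). The cell cycle inhibitor gene CDKN1A rose by 0.46 and GDF15 fell by 0.37. Of these targets 1 fell without any 1 array other than normal HDL replicate 3, and 3 fell without it. Of 15 genes of microRNA processing and silencing, 4 rose and 4 fell, and 4 rose and 5 fell adjusted over the list alone (adjusted p = 0.856, median 0.06, mean -0.03). The Argonaute genes AGO3 (-0.64, on 1 of 4 probe sets) and AGO2 (-0.39) fell, and TARBP2 rose by 0.27. Over the fits without 1 array, 1 to 3 genes of this list rose and 2 to 5 fell, with 1 and 2 without FH HDL replicate 3, and no rise was called with median-centred arrays, where 2 fell, or with the mean of a gene's probe sets, where 3 fell.

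Of 9 heat shock protein genes, 2 rose and 0 fell, and 1 rose adjusted over the list alone (adjusted p = 0.259). HSPB1 (0.27) lost its call without normal HDL replicate 2 or any 1 array of FH HDL (0.25 to 0.27, adjusted p from 0.0505 to 0.0595), and DNAJB1 (0.17) without any 1 of the 6 arrays. Of 21 nuclear subunits of oxidative phosphorylation, 2 rose and 2 fell, and 0 changed adjusted over the list alone (adjusted p = 0.524). Over the fits without 1 array, 0 to 1 rose and 0 to 2 fell, and no call was left without normal HDL replicate 2 or without FH HDL replicate 3. Ribosomal protein genes lay between -0.15 and 0.12, with 0 of 17 higher and 1 lower, and 0 lower adjusted over the list alone (adjusted p = 0.734). The 1 call, of RPL10A (-0.15), was lost without any 1 of the 6 arrays. Among markers of other cell types, 1 of 6 blood and platelet genes rose, also adjusted over the list alone (CD14, 0.47; list adjusted p = 0.661), and 1 of 6 stromal and endothelial genes rose, 0 adjusted over the list alone (DCN, 0.46; list adjusted p = 0.734). CD14 lost its call without FH HDL replicate 2 (0.44, adjusted p = 0.0519), and without normal HDL replicate 2 or 3, 2 blood and platelet genes rose. DCN lost its call without any 1 array other than normal HDL replicate 2, at 0.35 to 0.53 (adjusted p from 0.0756 to 0.121). Camera called 7 of the 24 lists in all, 3 higher and 4 lower, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes moved one way on balance and does not compare them with other genes, called 17.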

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

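The tests weighed here were written down after the main comparison and before their own results were seen. Those with the ACTB control difference as a covariate are the exception, as they were chosen only after their results were seen. Of the 18 ATF4 genes 4, and of the 17 genes of the chaperone list 8, stood in lists whose values had been seen. So did 1 of the 9 glucocorticoid targets. Probe sets outside the gene comparison also differed between the groups: 652 of 3484 tested probe sets with no gene listed in the annotation passed an adjusted p under 0.05, 375 of them higher with FH HDL and 277 lower. Of 1066 probe sets listed with several genes, 303 passed. Neither kind entered the counts of genes.

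With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 4226 changed genes, the highest other split 0, and 1 of the 10 splits, the real one, reached the real count. For the 1.5-fold rule the counts were 618 and 54, and for gene lists 7 and 5, each again reached by the real split alone. Every other split called 1 to 5 lists, although each gave 0 changed genes. Camera at the preset correlation thus called lists where no gene was called.

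For the rise of DNA replication genes, the lower of the list medians with the values as deposited and with median-centred arrays was 0.81, against 0.83. The rise thus did not depend on the choice among these scalings. Array medians lay between 6.44 and 6.58, so the test could hardly have come out otherwise. The processing before deposit is not known and was not tested. With the ACTB control difference as a covariate, 52.6% of genes moved by more than their SE, while the list median was 0.86, with a median SE of a gene of 0.14, and camera called the list (adjusted p = 3.91e-08, within a range of 1.29e-10 to 5.53e-07 over the alternatives with a preset correlation), with 10 genes called instead of 17. This argues against a trend with that control as the whole source, although the list was not called with an estimated correlation (adjusted p = 0.343 with an estimated correlation). The highest median of 10000 random lists matched on mean expression was 0.33, which decides nothing, as the list was picked for standing apart from other genes, so RNA handling that the control does not track stays open. A difference in growth of the cultures with FH HDL may account for the pattern and is an untested biological explanation.

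The fall of metallothioneins could come from 1 changed member read by all probe sets: among probe sets of the type without shared targets, 1 member gene (MT1M) was measured and it fell, so the number of genes that fell cannot be told apart from a single one. A lower supply of metal would also lower SLC30A1, a zinc exporter induced by the same metal sensor, and it fell by 0.69 (adjusted p = 0.000671), which is consistent with that hypothesis. Glucocorticoids also induce metallothioneins: 9 of their targets had a median of -0.055, with 2 higher and 3 lower. That list was not called by limma's camera. Its median lay above that of the metallothioneins by more than the SD of 0.40 among the targets. The outcome written beforehand as speaking against lower glucocorticoid signalling was not met, because the median of the targets was negative. The test thus does not decide. As 3 of the targets fell, a part played by glucocorticoids stays open. The metal content of the 2 kinds of HDL and of the medium was not measured in the data used here.

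The fall of stress-response genes lay at -0.35, or -0.25 with the mean of a gene's probe sets. With the ACTB covariate the median was -0.38, with a median SE of a gene of 0.09 against 0.06, and camera called the list (adjusted p = 0.000112, within a range of 3.74e-05 to 0.0427 over the alternatives with a preset correlation; adjusted p = 0.25 with an estimated correlation), which argues against a trend with that control as the whole source, while 4 genes instead of 12 were called lower. The lowest of 10000 matched random lists lay at -0.34, which decides nothing for the reason given for replication. An arm driven by ATF4 may be the part that moved. The list of its targets, not all of which supply amino acids, had a median of -0.38, with 15 of 18 lower and 0 higher. The 14 outside the fixed lists had a smaller one of -0.21, with 11 lower (camera adjusted p = 0.0731 with an estimated correlation for the 18). The list of chaperones of the endoplasmic reticulum, not all of whose genes are chaperones, did not fall as a set. Its median was 0.17, above the stress list by more than the SD of 0.43 among its genes, and 0.089 with the ACTB covariate. For the 9 outside the fixed lists it was 0.23, with an SD of 0.30. This argues against a fall of chaperones as the whole source. Of the 17 genes of that list 8 stand in the fixed lists too. Among them HERPUD1, which acts in degradation, DNAJB9 and SEL1L fell, so a part played by these stays open. RNA handling that the control does not track and a biological effect of FH HDL both stay open.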

How the results depend on the processing

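Of 103 named genes that were called, 101 kept their direction under every alternative that measured them, and 85 kept their call whichever array was left out. The ACTB covariate ended the calls of 51 of the named genes, the replicate block and the mean of a gene's probe sets of 20 each, and median-centred arrays of 16. FOXA2 (0.018) and DNAJB1 (-0.059) changed sign with the mean of a gene's probe sets, and ALB did so (0.19) without shared-target probe sets; the other probe sets of these genes differ from the one used. Leaving out 1 array gave 1343 to 2100 genes higher and 1233 to 1883 lower, the fewest without FH HDL replicate 3, where fewer arrays were fitted. With no filter 430 genes fell by the 1.5-fold rule, in a wider set of genes. Median-centred arrays gave 1344 genes higher, and the mean of probe sets gave 223 higher by the 1.5-fold rule; the cause was not tested. At probe set level, with more features tested, 3650 were higher and 3722 lower, and 717 and 930 by the 1.5-fold rule. A fold of 2 left 31 and 34 and a fold of 1.2 gave 1998 and 1589, as the rule itself sets. The ACTB covariate, added after the data were seen, gave 335 and 367, and 570 and 420 by the 1.5-fold rule; it takes 1 residual degree of freedom and itself differs between the groups. With the replicate block, 1334 genes were higher and 1173 lower, and no list call changed. Deviations of arrays with equal numbers correlated at -0.31, -0.03 and -0.13, and those with unequal numbers at -0.24 to 0.29. No effect shared by equal numbers was thus seen, and whether the numbers pair the cultures is not known. An estimated correlation called 0 lists and fry 17. Another scaling left 49.8% to 59.8% of changed genes higher. Dim genes near the filter of 5.99 are limited by their signal over background. The planned seed-site test and the pseudocount alternative were not run.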

Other observations

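All tests in this part used gene lists written after the main comparison had been seen. Of the 18 ATF4 genes 4, of the 17 genes of the chaperone list 8 and of the 14 FOXO targets 1 stand in the fixed lists as well. The values of these genes were thus not unseen. A list of targets of the transcription factor ATF4, not all of which supply amino acids, was lower with FH HDL. Of its 18 genes 15 fell and 0 rose, and 16 fell and 1 rose adjusted over the list alone, with a median of -0.38. CEBPB (-0.73), STC2 (-0.73), the amino acid transporter subunit SLC3A2 (-0.69) and the folate enzyme MTHFD2 (-0.63) fell most, while ATF4 itself was not called (-0.10). Camera gave an adjusted p of 6.08e-08 for the list, and adjusted p = 0.0731 with an estimated correlation. For the 14 of these genes outside the fixed lists, 11 fell, the median was -0.21 and the unadjusted camera p was 1.47e-06, or 0.0426 with an estimated correlation. With the ACTB covariate 6 of the 18 fell, with a median of -0.37 and a median SE of a gene of 0.10, against 0.06. Of 17 genes of the list of endoplasmic reticulum chaperones, not all of which are chaperones, 7 rose and 3 fell, with a median of 0.17. The list was not called by limma's camera (adjusted p = 0.14, and adjusted p = 0.305 with an estimated correlation). CRELD2 (0.77) and MANF (0.73) rose most. With the ACTB covariate 3 of the 17 rose and 2 fell, with a median of 0.089 and a median SE of a gene of 0.09, against 0.06. Of the 9 genes of the chaperone list outside the fixed lists 5 rose and 0 fell, with a median of 0.23. Their unadjusted camera p was 0.00385, upward, or 0.0398 with an estimated correlation. The members named in this part were chosen after their values were seen.

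A hypothesis for the falls of FBXO32 and PDK4 is lower activity of FOXO transcription factors, which insulin signalling restrains. Of 14 other FOXO targets, 10 fell and 0 rose, and 12 fell adjusted over the list alone, with a median of -0.34 (camera adjusted p = 8.16e-06; adjusted p = 0.0609 with an estimated correlation). IRS2 (-0.84), KLF15 (-0.82), KLF9 (-0.71), IGFBP1 (-0.51) and the insulin receptor gene INSR (-0.45) were among them. With the ACTB covariate 1 of the 14 was called, while the median was -0.41, 0 of the 14 lay above 0 and the median SE of a gene was 0.10, against 0.06. Without FH HDL replicate 3, 6 were called, the median was -0.32 and the median SE 0.07. The test could have come out the other way, and the hypothesis may stand. Insulin, growth factors and the FOXO proteins themselves were not measured.

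A hypothesis for the rises of ID1 and ID3 is BMP signalling, which induces both. Of 8 other BMP targets, 3 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone, with a median of 0.11. Limma's camera did not call the list (adjusted p = 0.422). SMAD6 (0.66), SMAD9 (0.58) and ID4 (0.43) rose and ID2 fell by 0.31. Without normal HDL replicate 2 or without FH HDL replicate 2, 1 target rose, without FH HDL replicate 3, 2 rose, and no fall was called in these fits. With the ACTB covariate 0 of the 8 targets rose and 0 fell by call, while 7 lay above 0 and the median was 0.20. The median SE of a gene was 0.16 in that fit, against 0.12. The hypothesis stays open.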
